A study of Homo sapiens with 2 samples.

How the data were processed

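Each of the 2 libraries was deposited as a matrix of whole-number counts of UMIs for 36601 genes and 6794880 barcodes, made with Cell Ranger 4 per the file headers and aligned to GRCh38 (hg38) per the submitters' processing notes. The deposited counts are not normalized and no barcode filter had been applied. The labels give 1 library for each treatment, LacZ and aSyn, taken from the treatment label. They name the organism as human while the series text speaks of mouse brain. The matrices hold human genes, and mouse RNA was not analysed here. Per the labels' protocols a 10x Genomics 3' kit was used.

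Free RNA was abundant. Barcodes with 300 to 999 UMIs held 62.2% of LacZ and 48.2% of aSyn UMIs, with medians of 554 and 631 UMIs. A barcode counted as a cell with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Scrublet marked 0.330% of LacZ and 0.0105% of aSyn cells as doublets, under the 0.5% at which it was taken to have worked, so the cells with the highest scores were removed instead, 0.8% per 1000 cells (105 and 719 cells). Both libraries were clustered together with scanpy 1.11.5 (10000 UMIs per cell, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, no integration). XIST and Y-linked genes were left out. With at least 2000 or 4000 UMIs per cell Scrublet's own threshold held for LacZ and the highest scores for aSyn, so the removal differed between libraries there.

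Clusters were named from markers fixed before the data were examined. A name needed 3 markers raised at least 1.5-fold and at least 1 marker among the 10 leading genes by fold. This last number was tightened from 25 to 10 after the clusters had been seen. Cluster 3 (7.54% of LacZ and 7.16% of aSyn cells, led by NEAT1 and SCN1A) had no marker of its best list among the 10 or the 25 leading genes and stayed unnamed. A limit on the share of background was also set then. Clusters 0 (33.4% and 27.9%) and 6 (24.6% and 20.5%) had under 3 raised markers. Background made up an estimated 50.0% of the median UMIs of a cell in cluster 0 and 35.4% in cluster 6.

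UMIs were summed per class and library and divided by the class total, giving CPM. The log2 ratio of aSyn over LacZ has an exact interval for a ratio of Poisson counts. A count of 0 was set to a floor of 3 counts in a ratio. Genes needed 100 UMIs over both libraries. Class totals in neuron-like cells were 3041231 UMIs in LacZ and 13743612 in aSyn, and in astrocyte-like cells 8529270 and 13147947. A list's median is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Named genes were the 12 highest and 12 lowest in neuron-like cells by the interval bound nearest to equality, the 5 highest and 5 lowest in other classes and over all cells, and the list members with the largest ratios. XIST, Y-linked, mitochondrially encoded and cytosolic ribosomal protein genes were left out of that ranking. Some genes that these rules name are not reported here.

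The ratios, intervals and list percentiles were tested on simulated Poisson counts drawn from the summed counts of both libraries with genes changed 2-fold. Cell calling, clustering and naming were not simulated, nor was variation between cells or libraries. The simulation therefore does not show how well the intervals cover real counts. In the simulation of neuron-like cells 9987 genes were measured, 100% of 187 changed genes had the right direction, and intervals held the true value for 94.1% of changed and 95.4% of other genes. In that of astrocyte-like cells (11130 genes) they held it for 93.8% and 95.8%. A random list of unchanged genes fell at percentile 51.0 in the first and 97.65 in the second, so a single list outside the central 95% can arise by chance.

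Alternatives chosen beforehand changed the UMI minimum, the mitochondrial limit, doublet removal, the Leiden resolution, the scaling, the weight of cells, depth, background subtraction and the UMI minimum per gene. Background subtraction with barcodes of 300 to 600 UMIs, a minimum of 4000 UMIs per cell, clustering without genes 2-fold apart and each astrocyte-like cluster alone were added after seeing the data. Transcript lengths and coordinates came from GENCODE 29. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 were used.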

Results

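Single-cell RNA sequencing with the 10x Genomics 3' assay, in which each captured RNA molecule carries a unique molecular identifier (UMI), was deposited for 2 human brain-derived samples that the labels call oligodendrocytes of wild-type genotype. The LacZ sample received LacZ, the bacterial beta-galactosidase gene commonly used as an inert control, and the aSyn sample received the treatment that the labels call aSyn. Levels are UMIs of a gene per 1000000 UMIs of the class (CPM). There was 1 library per treatment, so no difference has a replicate check, no test was made and every comparison is between 2 libraries. Intervals of gene levels, gene ratios and cell shares are exact 95% intervals and cover counting error only. The LacZ matrix held 60893496 UMIs and the aSyn matrix 91799936. After filters, 3526 LacZ cells and 8763 aSyn cells remained, with medians of 2075.5 and 2252 UMIs and 1190.5 and 1277 genes per cell.

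Neither library held a cluster with the expression profile of oligodendrocytes. Cells fell into neuron-like, astrocyte-like and dividing cell-like classes and into clusters that stayed unnamed. MBP, the main structural protein of myelin, had 3 UMIs over all LacZ cells and 12 over all aSyn cells. MOG, a myelin surface protein, had 2 and 3 UMIs. MAG and OPALIN had 0 UMIs in both libraries, below the floor of 3 counts, which is 0.171 CPM in LacZ and 0.0741 in aSyn. The exact upper bounds were 0.210 and 0.0911 CPM. The microglial genes C1QA, P2RY12 and TYROBP had 0 UMIs in both libraries. By the rule fixed for this case, the named class with the most cells over both libraries, neuron-like cells, served as the main class.

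Neuron-like cells made up 14.4% of LacZ cells (509 cells, exact binomial interval 13.3% to 15.6%) and 26.9% of aSyn cells (2361 cells, 26.0% to 27.9%). Their cluster was led by SCGN, STMN2, NSG1, INA and CALB2. Astrocyte-like cells made up 17.4% of LacZ cells (613 cells, 16.1% to 18.7%) and 13.2% of aSyn cells (1157 cells, 12.5% to 13.9%), in a cluster led by CLU and PTPRZ1 and another led by TAGLN and RAB31. The first (cluster 4) held 262 LacZ and 370 aSyn cells and the second (cluster 5) 351 and 787, so their mix differed between the libraries. Dividing cell-like cells made up 2.67% (94 cells, 2.16% to 3.25%) and 4.31% (378 cells, 3.90% to 4.76%). At higher minima the intervals overlapped: the shares were 2.86% and 3.26% with at least 2000 UMIs per cell and 4.12% and 4.35% with 4000. There a cluster led by TAC3 and NPY was apart from the class. It held 54 LacZ and 237 aSyn cells at 2000 UMIs and 97 and 425 at 4000. The dividing cell-like class then held 53 and 158 cells, and 48 and 140, so these shares are not for the same cells. With at least 500 UMIs no such share is comparable, since dividing cells shared a cluster led by RAB31 and TAGLN there. Unnamed clusters held 65.5% of LacZ cells and 55.5% of aSyn cells. Some genes that define the clusters, TAGLN among them, differed between the libraries. Clustered without the 161 genes that differed at least 2-fold over all cells, the neuron-like shares were 14.3% and 25.1% and the astrocyte-like shares 16.6% and 13.6%. All shares depended on the minimum number of UMIs per cell, and with at least 4000 UMIs the neuron-like shares were 23.4% and 34.2%.

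**Figure D1:**
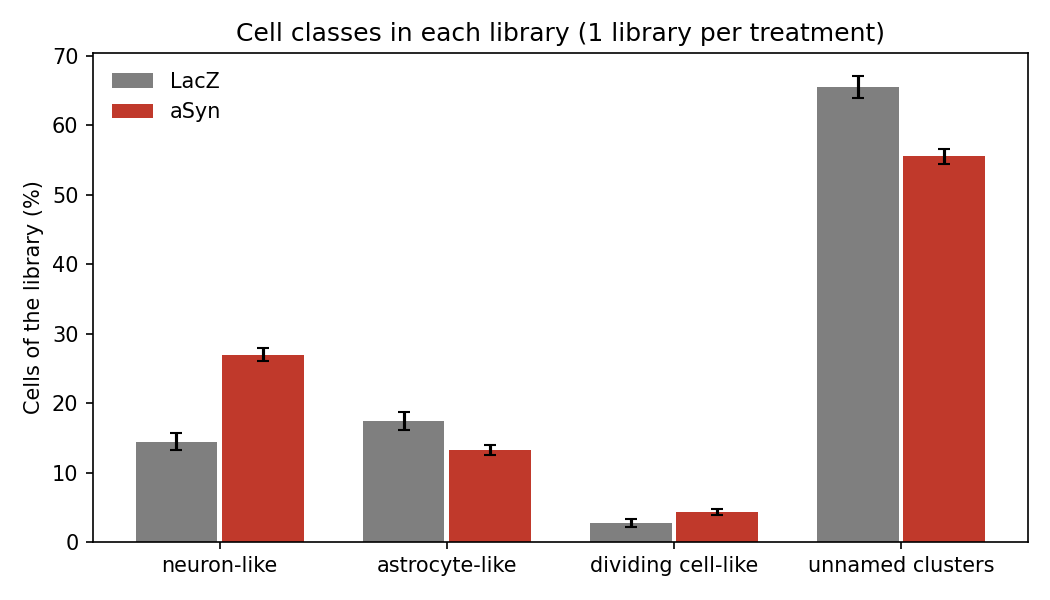
Share of cells (%) in each class for the LacZ and aSyn libraries, with bars for shares and error bars for exact binomial 95% intervals. The neuron-like share was 14.4% in LacZ and 26.9% in aSyn.

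The comparison of the treatments asked which genes differed between the libraries in neuron-like cells. Most genes were close to equal: of 10013 genes with at least 100 UMIs, 94.5% had a log2 ratio of aSyn over LacZ within 0.5 of 0, while 13 were at least 2-fold higher and 16 at least 2-fold lower. The higher count was 27 with background subtracted and 30 as the mean of each cell's share, and the lower count was 6 with each cell thinned to 1000 UMIs. These counts describe the libraries and are not counts of changed genes. PCP4 (ENSG00000183036, chromosome 21, 39867317 to 39929397, GRCh38 with GENCODE 29), a calmodulin-binding protein, was 7.56 CPM in LacZ and 26.8 in aSyn (log2 ratio 1.82, with 1.22 as the lower bound). APOE, a lipid carrier made largely by glia, was 33.9 and 64.0 (0.92, 0.62 to 1.23). TAC3, which encodes neurokinin B, was 261 and 419 (0.68, 0.57 to 0.79). The other genes named as higher were METRN (0.67), TNC (1.31), HOPX (0.71), NEAT1 (1.28), LINC-PINT (1.25), PRDX1 (0.49), POU3F2 (0.94) and GYG1 (1.02). PCP4, APOE, METRN, TNC, HOPX, PRDX1, POU3F2 and GYG1 were higher in background barcodes of 300 to 600 UMIs than in neuron-like cells of the same library. Background made up an estimated 9.27% of LacZ and 10.8% of aSyn UMIs of the class. At those shares background alone would give 56.9 CPM of HOPX in LacZ and 84.5 in aSyn, against 59.2 and 96.6 measured, and 27.5 and 42.2 CPM of APOE. TNC, NEAT1, LINC-PINT and GYG1 were on the other side of 0 over all cells.

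Among the genes named as lower in aSyn neuron-like cells, MTRNR2L12 was 1535 CPM in LacZ and 617 in aSyn (log2 ratio -1.32, -1.37 to -1.26). It and MTRNR2L8 (-1.002) are near-copies of the mitochondrial gene MT-RNR2, so their counts are uncertain. SNHG25, a host gene of small nucleolar RNA, was 123 and 51.0 (-1.27, -1.45 to -1.08), and PLCG2, a phospholipase of receptor signalling, was 260 and 125 (-1.05, -1.18 to -0.93). HIST1H4C, a histone gene, was 760 and 433 (-0.81, -0.88 to -0.74). The remaining genes were AL627171.2 (-1.06), TRIM56 (-1.31), ZFHX2-AS1 (-1.18), SNHG9 (-0.79), RC3H1 (-0.84), MATR3 (-0.95) and MROH8 (-0.96). MATR3 has 2 entries in the annotation that can split its reads, and ZFHX2-AS1 is antisense to another gene. MTRNR2L12, SNHG25, MTRNR2L8, AL627171.2, HIST1H4C and SNHG9 were also higher in background barcodes than in neuron-like cells, and lower in those of aSyn: MTRNR2L12 was 2246 and 1118 CPM there and SNHG25 192 and 92.0.

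Gene lists fixed before the data were examined gave small medians in neuron-like cells. The 13 mitochondrially encoded genes were all lower in aSyn, with a median log2 ratio of -0.39 (percentile 0 among 10000 random lists matched on expression), led by MT-ND6 (-1.21), MT-ATP8 (-1.17) and MT-ND4L (-0.85). MALAT1, a nuclear RNA, took 7.07% of the UMIs of LacZ and 5.56% of those of aSyn neuron-like cells, and ribosomal protein genes 15.6% and 16.7%. Of 23 cholesterol synthesis genes, 21 were lower, with a median of -0.24 (percentile 0), including DHCR7 (-0.54), INSIG1 (-0.45) and SQLE (-0.36). That median was 0.028 with at least 2000 UMIs per cell and -0.061 at Leiden resolution 1, and in both a cluster led by HIST1H2AC was separate and unnamed. Of 33 proteasome genes 28 were higher, with a median of 0.13 (percentile 99.8), including PSMA6 (0.27) and PSMA1 (0.26). Oxidative stress and iron handling genes had a median of 0.16 (percentile 99.2, 12 of 18 higher), with NQO1 at 0.53 and TFRC at -0.53. Cytosolic ribosomal protein genes had a median of 0.14 (percentile 99.5, 60 of 77 higher), with RPS29 (-0.60) and RPS10 (-0.46) going the other way. Other transcripts under 1000 nt had a median of 0.11 in these cells, 0.18 above those over 3000 nt. The random lists were not matched on length, so the ribosomal median is not separated from that gap. Percentiles of the other lists, in every class, carry the same limit. Synapse and neuronal transcripts had a median of -0.12 (percentile 1.845), with NEFL at -0.38 and GRIA2 at -0.26.

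The other lists lay within the central 95% of their random lists in neuron-like cells. Their median log2 ratios were -0.05 for myelin proteins and lipids, 0.07 for oligodendrocyte progenitor state, 0.08 for endoplasmic reticulum chaperones, -0.04 for the integrated stress response and 0.04 for heat shock. They were -0.03 for immediate early genes, -0.08 for interferon response, 0.04 for MHC class I, 0.06 for NF-kappa-B signalling and 0.13 for disease-associated oligodendrocyte genes. They were 0.09 for nuclear-encoded oxidative phosphorylation, 0.06 for glycolysis, 0.05 for lysosome and autophagy, 0.08 for p53 response and 0.09 for genes of inherited Parkinson disease. Several of these medians moved under alternatives. With each cell thinned to 1000 UMIs they were 0.51 for MHC class I, 0.17 for glycolysis, 0.12 for nuclear-encoded oxidative phosphorylation and -0.11 for p53 response. Thinning lowers the summed UMIs, so lists can keep fewer members over the UMI minimum per gene. These thinned medians therefore need not be for the same genes. The p53 median was 0.22 and 0.27 at minima of 2000 and 4000 UMIs and 0.21 at Leiden resolution 1, and nuclear-encoded oxidative phosphorylation was 0.051, 0.056 and 0.063 there. The immediate early median was 0.15 at the minimum of 2000 UMIs, that of the integrated stress response 0.11 with at least 400 UMIs per gene, and that of disease-associated genes 0.24 as the mean of each cell's share. Axon-glia contact and matrix genes had -0.11 and cytoskeleton genes 0.09. MHC class II genes had too few measured members.

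Astrocyte-like cells differed more. Of 11123 genes, 23 were at least 2-fold higher and 46 at least 2-fold lower in aSyn. These counts were 42 and 80 as the mean of each cell's share and 11 and 22 with each cell thinned to 1000 UMIs, and the higher count was 35 with doublets kept, 37 with at most 10% mitochondrial UMIs and 10 in cluster 4 alone. SEZ6L, a neuronal membrane protein, was 32.7 CPM in LacZ and 92.6 in aSyn (log2 ratio 1.501, 1.31 to 1.69). PCP4 (1.57), SCGN (1.54) and C11orf96 (1.33) were the other genes named as higher. These 3 were higher in background barcodes than in astrocyte-like cells, with SCGN at 358 and 446 CPM there against 16.4 and 47.8, while background made up an estimated 3.98% of LacZ and 5.55% of aSyn UMIs of the class. COL26A1 (ENSG00000160963, chromosome 7, 101362820 to 101559024), a collagen, was 71.0 and 20.9 (-1.76, -1.98 to -1.56). CCN1, a matrix protein induced by mechanical signals, was 217 and 75.1 (-1.53, -1.65 to -1.42), and THBS1, a matrix glycoprotein, was 43.0 and 14.5 (-1.57, -1.83 to -1.32). RGS5 (-1.89) and SLC26A7 (-1.67) were also lower. At those shares background alone would give SCGN, a leading gene of the neuron-like cluster, 14.2 CPM in LacZ and 24.7 in aSyn astrocyte-like cells. Neuron markers had a median of 0.42 over 8 markers in astrocyte-like cells, with 6 higher and 2 lower in aSyn. Background was not subtracted for this median. Dividing cell markers were lower, at -0.47 over 13 (10 lower). Pericyte and fibroblast-like markers were also lower, at -0.68 over 6 (5 lower).

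In astrocyte-like cells the 4 measured genes of antigen presentation by MHC class II were all lower in aSyn, with a median log2 ratio of -1.45 (percentile 0). CD74, the class II invariant chain, was -1.56 (-1.87 to -1.26), HLA-DRA -1.43 (-1.65 to -1.21), HLA-DPA1 -1.47 and HLA-DRB1 -1.11. HLA genes vary between people, which can change how many of their reads are counted. Endoplasmic reticulum chaperones (median -0.15, percentile 0.13, 18 of 22 lower) included XBP1 (-0.46) and HYOU1 (-0.45). Oxidative stress and iron handling genes (0.27, percentile 100, 19 of 23 higher) included MT3 (1.18) and GCLC (0.81). Proteasome genes (0.18, percentile 99.99, 30 of 33 higher) included PSMB3 (0.33) and PSMA4 (0.31). Integrated stress response genes had a median of 0.22 (12 of 16 higher), with VLDLR at -0.92 and NUPR1 at 0.75, p53 response genes 0.20 (15 of 18 higher), with BCL2 at -1.03 and FAS at -0.41, and immediate early genes -0.19 (12 of 16 lower), with ARC at 1.25 and FOSL2 at -0.90. The immediate early median was 0.053 with at least 500 UMIs per cell, where the class held other cells, a single cluster led by NEAT1 and SCN1A. Medians were -0.17 for mitochondrially encoded genes (13 of 13 lower), 0.13 for nuclear-encoded oxidative phosphorylation, 0.12 for ribosomal protein genes, -0.06 for lysosome and autophagy and -0.10 for axon-glia contact. The mitochondrially encoded median was 0.15 in cluster 4 alone and the lysosome median 0.012 in cluster 5 alone.

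**Figure D2:**
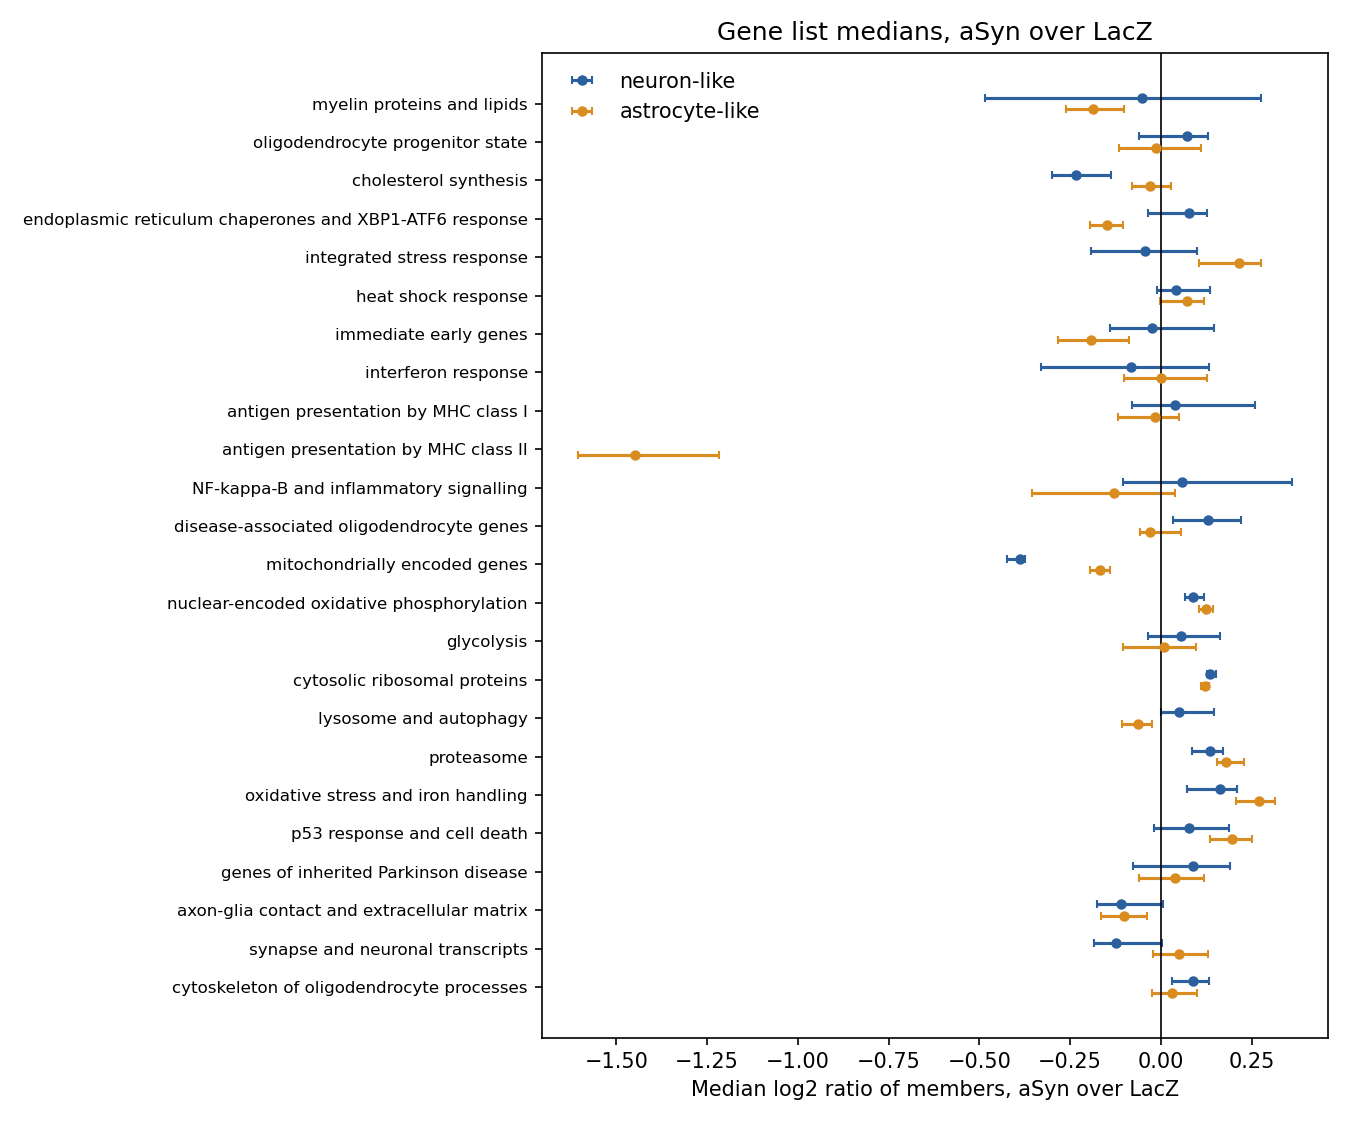
Median log2 ratio of aSyn over LacZ for each gene list in neuron-like and astrocyte-like cells, with points for medians and error bars for 95% intervals from Poisson resampling of counts. The mitochondrially encoded list lay at -0.39 in neuron-like cells, and MHC class II lay at -1.45 in astrocyte-like cells.

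Dividing cell-like cells, with 94 LacZ cells, had 31 genes at least 2-fold higher and 53 at least 2-fold lower in aSyn among 7725. With each cell thinned to 1000 UMIs 9 were higher and 2 lower. Thinning lowers the summed UMIs, so fewer genes reach the UMI minimum per gene and these counts are for a smaller set. Whether the larger number of lower genes holds at equal depth is therefore open. GAS1 (log2 ratio 1.32), NMB (1.15), DLL3 (1.26), a Notch ligand, and TAC3 (0.99) were named as higher. TAGLN, an actin-binding protein of contractile cells, was 276 CPM in LacZ and 48.0 in aSyn (-2.52, -2.76 to -2.29). CCK (-2.15), CCN1 (-2.24), PRSS23 (-1.73) and A2M (-1.56) were also lower. Dividing cell markers had a median of -0.29 in this class (13 of 16 lower) and neuron markers 0.23 (7 of 9 higher).

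Over all cells, which needs no class names, 13449 genes were measured. The genes named as higher were DHRS3, an enzyme of retinoid metabolism (5 UMIs in LacZ and 202 in aSyn, log2 ratio 4.13, 2.89 to 5.77), GSX1 (2.08), PCP4 (1.29) and TPPP3 (1.69). Those named as lower were CCN2 (-3.69), COL26A1 (-2.12), GRHL3 (-2.42), CCN1 (-1.95) and RGS5 (-2.16). MHC class II genes had a median of -1.80 (5 of 5 lower), MHC class I genes -0.42 (13 of 14 lower), mitochondrially encoded genes -0.31 (13 of 13 lower) and proteasome genes 0.22 (30 of 33 higher). These medians also carry the difference in class shares, and neuron markers had a median of 0.53.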

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

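Barcodes with 300 to 600 UMIs, which the filters leave out of the cells, held RNA of several genes at a higher level in aSyn than in the LacZ control. The log2 ratios were 0.94 for PCP4, 1.05 for SERPINE2, 0.67 for METRN and 1.06 for CDC42EP2. Larger differences went the other way, with -1.79 for THBS1, -1.65 for CCN1, -1.59 for COL26A1, -1.52 for TAGLN and -1.49 for BOLA2B. Of 11847 genes measured there, 3 were at least 2-fold higher and 54 at least 2-fold lower in aSyn. Barcodes of 1 to 100 UMIs had 25 higher and 29 lower of 7037 genes, with a median log2 ratio of 0.13. Fewer genes were measured in them. In LacZ 2513516 such barcodes held 4691779 UMIs, so most held very few and need not be droplets of free RNA. Whether the surplus of lower genes is general to free RNA is therefore open.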

How the results depend on the processing

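The alternatives with barcodes of 300 to 600 UMIs as background, at least 4000 UMIs per cell, clustering without genes 2-fold apart and each astrocyte-like cluster alone were chosen after seeing the data, the others before. No paired analysis was possible because each treatment had 1 library. Of the values that answer a comparison, 672 stayed within their counting interval or within 1.5 times a count under an alternative, 148 moved and 4 reversed. For single named genes and lists of other classes these numbers were 1316, 258 and 12. Counts of genes 2-fold apart changed with the UMI minimum per gene, which alters both how many genes are measured and their counting error. These were not told apart. For the other values in this part the cause was not tested either. The neuron-like share stayed higher in aSyn under every alternative run, although at Leiden resolution 1 and with at least 2000 or 4000 UMIs per cell a cluster led by HIST1H2AC was apart from the class and unnamed. The astrocyte-like class did not hold the same cells throughout. With at least 500 UMIs per cell it was a single cluster led by NEAT1 and SCN1A, and cells led by RAB31 and TAGLN were in the dividing cell-like class, so the values of both classes there are not for the cells of the report. With at most 10% mitochondrial UMIs the astrocyte-like class held a cluster led by NEAT1 and SCN1A and none led by CLU and PTPRZ1. With at least 4000 UMIs per cell it held a cluster led by NEAT1 and CLU. In the other alternatives that changed the clusters, the astrocyte-like share stayed higher in LacZ. An alternative that left a gene or list under its UMI minimum gave no value. With at least 2000 or 4000 UMIs per cell a cluster led by TAC3 and NPY was apart from the dividing cell-like class. Depth limits dividing cell-like cells most, with 94 cells in LacZ.

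With at least 500 UMIs per cell, cells numbered 6282 in LacZ and 16678 in aSyn, and the neuron-like share was 7.96% in LacZ and 13.3% in aSyn. Under at least 500 UMIs per cell also, the astrocyte-like share was 9.11% in LacZ and 7.11% in aSyn, and the dividing cell-like share was 7.45% in LacZ and 7.57% in aSyn, and list medians for astrocyte-like cells were immediate early 0.053, and genes 2-fold apart in dividing cell-like cells were 67 higher, and list medians for all cells were disease-associated -0.25, mitochondrial -0.29 and cytoskeleton 0.12. With at least 2000 UMIs per cell, cells numbered 1852 in LacZ and 4842 in aSyn, and the neuron-like share was 25.4% in aSyn. Under at least 2000 UMIs per cell also, the astrocyte-like share was 30.5% in LacZ and 23.5% in aSyn, and the dividing cell-like share was 3.26% in aSyn, and list medians for neuron-like cells were cholesterol 0.028, immediate early 0.15, mitochondrial -0.49, nuclear OXPHOS 0.051, ribosomal 0.12 and p53 0.22, and list medians for all cells were ER chaperones -0.30, disease-associated -0.32, mitochondrial -0.34, nuclear OXPHOS 0.15, ribosomal 0.16 and proteasome 0.23. With at least 4000 UMIs per cell, cells numbered 1164 in LacZ and 3217 in aSyn, and the neuron-like share was 23.4% in LacZ and 34.2% in aSyn. Under at least 4000 UMIs per cell also, the astrocyte-like share was 39.1% in LacZ and 25% in aSyn, and the dividing cell-like share was 4.12% in LacZ, and list medians for neuron-like cells were cholesterol -0.053, mitochondrial -0.47, nuclear OXPHOS 0.056, ribosomal 0.11 and p53 0.27, and list medians for all cells were ER chaperones -0.33, disease-associated -0.39, mitochondrial -0.38 and lysosome -0.25. At Leiden resolution 1, the neuron-like share was 9.9% in LacZ and 16% in aSyn, and the astrocyte-like share was 15.7% in LacZ and 11% in aSyn. At Leiden resolution 1 also, the dividing cell-like share was 3.57% in LacZ and 5.4% in aSyn, and list medians for neuron-like cells were cholesterol -0.061, mitochondrial -0.45, nuclear OXPHOS 0.063, ribosomal 0.12 and p53 0.21. Clustered without genes 2-fold apart, the neuron-like share was 25.1% in aSyn. With at most 10% mitochondrial UMIs, the astrocyte-like share was 24% in LacZ and 21% in aSyn, and genes 2-fold apart in astrocyte-like cells were 37 higher. Under at most 10% mitochondrial UMIs also, list medians for all cells were mitochondrial -0.30. With doublets kept, the dividing cell-like share was 3.59% in aSyn, and genes 2-fold apart in astrocyte-like cells were 35 higher. As the mean of each cell's share, genes 2-fold apart in neuron-like cells were 30 higher, and list medians for neuron-like cells were disease-associated 0.24, mitochondrial -0.35, nuclear OXPHOS 0.13 and ribosomal 0.16. As the mean of each cell's share also, genes 2-fold apart in astrocyte-like cells were 42 higher and 80 lower, and list medians for all cells were progenitor state -0.050, cholesterol -0.17, ER chaperones -0.12, immediate early -0.097, interferon response -0.12, MHC class I -0.29, disease-associated -0.13, mitochondrial -0.18, nuclear OXPHOS 0.10, lysosome -0.057, proteasome 0.18 and p53 0.13. With the background of 1 to 100 UMIs subtracted, genes 2-fold apart in neuron-like cells were 27 higher, and list medians for neuron-like cells were mitochondrial -0.45 and ribosomal 0.17. Under the background of 1 to 100 UMIs subtracted also, list medians for all cells were mitochondrial -0.34, ribosomal 0.15 and proteasome 0.23. With at least 50 UMIs per gene, genes 2-fold apart in neuron-like cells were 61 higher and 34 lower, and genes 2-fold apart in astrocyte-like cells were 57 higher and 86 lower. Under at least 50 UMIs per gene also, list medians for astrocyte-like cells were myelin 0.017, and genes 2-fold apart in dividing cell-like cells were 80 higher and 112 lower, and list medians for all cells were myelin -0.0091. With at least 400 UMIs per gene, genes 2-fold apart in neuron-like cells were 1 higher and 7 lower, and list medians for neuron-like cells were integrated stress response 0.11. Under at least 400 UMIs per gene also, genes 2-fold apart in astrocyte-like cells were 7 higher and 21 lower, and list medians for astrocyte-like cells were myelin 0.017, and genes 2-fold apart in dividing cell-like cells were 4 higher and 11 lower. With the background of 300 to 600 UMIs subtracted, genes 2-fold apart in neuron-like cells were 27 higher, and list medians for all cells were heat shock response 0.14. With each cell thinned to 1000 UMIs, genes 2-fold apart in neuron-like cells were 6 lower, and list medians for neuron-like cells were MHC class I 0.51, mitochondrial -0.36, nuclear OXPHOS 0.12, glycolysis 0.17, ribosomal 0.17, proteasome 0.20, p53 -0.11 and contractile 0.014. Under each cell thinned to 1000 UMIs also, genes 2-fold apart in astrocyte-like cells were 11 higher and 22 lower, and genes 2-fold apart in dividing cell-like cells were 9 higher and 2 lower, and list medians for dividing cell-like cells were lysosome 0.0060, and list medians for all cells were progenitor state -0.19, cholesterol -0.15, ER chaperones -0.20, immediate early -0.11, MHC class I -0.19, NF-kappa-B 0.036, disease-associated -0.11, mitochondrial -0.19, nuclear OXPHOS 0.099, lysosome -0.047, proteasome 0.18, oxidative stress 0.072 and p53 0.13. Over all cells instead of the class, genes 2-fold apart in place of those in neuron-like cells were 145 lower, and list medians in place of those for neuron-like cells were ER chaperones -0.24, immediate early -0.17, MHC class I -0.42, NF-kappa-B -0.25, disease-associated -0.29, mitochondrial -0.31, nuclear OXPHOS 0.12, glycolysis -0.10, lysosome -0.15, proteasome 0.22, synapse 0.025 and cytoskeleton 0.16. Over all cells instead of the class also, log2 ratios in place of those in neuron-like cells were TNC -0.090, NEAT1 -0.25, LINC-PINT -0.099 and GYG1 -0.14, and genes 2-fold apart in place of those in astrocyte-like cells were 145 lower, and genes 2-fold apart in place of those in dividing cell-like cells were 16 higher and 145 lower. With the median gene ratio set to 1, list medians for neuron-like cells were mitochondrial -0.37 and ribosomal 0.15, and list medians for all cells were heat shock response 0.13 and mitochondrial -0.30. In astrocyte-like cluster 4 alone, genes 2-fold apart in astrocyte-like cells were 10 higher, and list medians for astrocyte-like cells were myelin 0.081 and mitochondrial 0.15. In astrocyte-like cluster 5 alone, list medians for astrocyte-like cells were lysosome 0.012. With the total without mitochondrial and ribosomal genes, list medians for all cells were heat shock response 0.13.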

Other observations

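The tests in this part were chosen after the result was seen, except that of free RNA for the contractile genes, which was set down before its value was computed, although levels of some of these genes in background barcodes had been seen. The lists of contractile, interneuron, excitatory, ganglionic eminence and hindbrain genes were also written after the data had been examined.

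Neuron-like cells carried genes of inhibitory interneurons of the ventral forebrain in both libraries, though not all of these set the class apart. DLX2, a transcription factor of the ganglionic eminences, was 538 CPM in LacZ and 548 in aSyn, GAD1 102 and 94.2, and SLC32A1, the vesicular GABA transporter, 59.8 and 61.4. GAD1 was 78.3 and 113 CPM in astrocyte-like and 112 and 128 in dividing cell-like cells, below its neuron-like level only in LacZ astrocyte-like cells. DLX2 was 340 and 473 in dividing cell-like cells. SLC32A1 was lower there (19.2 and 16.9) and in astrocyte-like cells (2.93 and 3.42). SLC17A7, the vesicular glutamate transporter, had 0 UMIs in both libraries. NKX2-1, LHX6 and LHX8 had 0 UMIs in neuron-like cells of both libraries, as did HOXA2, HOXB4 and HOXC4. The interneuron list had a median log2 ratio of 0.0021 over 16 genes in neuron-like cells and 0.44 in astrocyte-like cells, without background subtraction. The excitatory, ganglionic eminence and hindbrain lists had too few measured members for a median. BCL11B of the excitatory and dorsal forebrain list, which ventral forebrain neurons also express, was 122 and 109 CPM in neuron-like cells.

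With at least 4000 UMIs per cell, an added setting, a cluster with oligodendrocyte progenitor markers separated, with 97 LacZ cells (8.33%) and 425 aSyn cells (13.2%). OLIG1, a transcription factor of the oligodendrocyte lineage, was 339 CPM in it and 91.4 in other cells, and PDGFRA, a receptor of oligodendrocyte progenitors, was 95.2 and 24.0. SOX10, which marks the oligodendrocyte lineage, had 0 UMIs in it, and DLX2 was 489 against 285. TAC3 (922 against 198), DLL3 (103 against 42.9) and GAS1 (78.6 against 18.3), which were higher in aSyn dividing cell-like cells, were also higher in this cluster. Within the cluster TAC3 was 728 CPM in LacZ and 970 in aSyn, DLL3 71.9 and 110, and GAS1 47.9 and 86.1. TAC3 was 505 and 1005 in the reported dividing cell-like class. Whether the make-up of that class carries its higher TAC3, DLL3 and GAS1 was not tested.

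A list of contractile and mechanically induced genes was lower in aSyn astrocyte-like cells, with a median log2 ratio of -0.70 and 24 of 24 members below 0. The list was chosen because genes of these kinds were low in aSyn. Its direction followed from that choice and is not independent support. The list also had medians of -0.60 in dividing cell-like cells (16 of 18 lower), -0.16 in neuron-like cells (11 of 15 lower) and -0.85 over all cells (25 of 25 lower). With each cell thinned to 1000 UMIs these were -0.082, 0.014 and -0.59, and -0.61 in astrocyte-like cells. Thinning can leave fewer list members over the UMI minimum, so these medians need not be for the same genes. At full depth 15 of 18 members had intervals below 0 in dividing cell-like cells and 0 above. In neuron-like cells 5 of 15 lay below and 2 above. Whether the pattern reaches the dividing cell-like and neuron-like classes at equal depth is therefore open. Pericyte and fibroblast-like markers, some of which the list shares, had -0.68 in astrocyte-like cells, and no test set such cells against a change within the class. The median was -0.684 after the background of 300 to 600 UMIs was subtracted. Background was an estimated 3.98% of LacZ and 5.55% of aSyn UMIs of the class, too small a share for the subtraction to move the median far. In barcodes of 300 to 600 UMIs CCN1 (-1.65) and TAGLN (-1.52) were also lower in aSyn, so the difference was not confined to cells of this class. A different mix of the astrocyte-like clusters leaves the lower median of the list, with medians of -0.58 and -0.63 within them and -0.578 where it was nearest to 0. Transcript length does not account for it either, since genes outside the list with the lengths of its members had a median of -0.002 (-0.010 to 0.010). With 1 library per treatment, the treatment and any other difference between the libraries cannot be told apart, so the pattern is a hypothesis only.

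The larger neuron-like share of aSyn kept its direction in the tests made. The ratio of the shares was 1.87 as reported, 1.463 with at least 4000 UMIs per cell, and 1.757 when clustered without the genes 2-fold apart. The share may follow the treatment or any other difference between the libraries, such as how many cells were loaded, and with 1 library per treatment these cannot be told apart.

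Several short RNAs, SNHG25 and RPS29 among them, were lower in aSyn, which led to the hypothesis that short transcripts were less well captured in that library. The test of this hypothesis left out ribosomal protein genes, RPS29 among them, and mitochondrially encoded genes. For the other transcripts the named classes did not bear it out. The median log2 ratio of transcripts under 1000 nt minus that of transcripts over 3000 nt was 0.18 in neuron-like and 0.085 in astrocyte-like cells, the opposite direction. It was 0.15 and 0.21 in the unnamed clusters 3 and 6 but -0.082 (-0.12 to -0.035) in the unnamed cluster 0, and -0.0073 over all cells (-0.032 to 0.026), which mixes these. In barcodes of 300 to 600 UMIs it was -0.034 (-0.064 to -0.0098), which crosses the bound of 0.05 set against a cause that acts on every droplet, and in barcodes of 100 UMIs or fewer it was -0.32 (-0.36 to -0.28). A difference in library preparation and the treatment therefore cannot be told apart with 1 library per treatment, and both stay open for cluster 0 and the barcodes with few UMIs.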
